A study of Canis lupus familiaris with 6 samples.

How the data were processed

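RNA was sequenced from MDCK cells, a canine kidney epithelial line, in 6 libraries. Wild-type cells and 2 mutant clones without PRL2 and heterozygous for PRL1 each received control siRNA or PRL1 siRNA, and RNA was taken 18 h after the second transfection. Per the labels' protocols, RNA was purified with miRNeasy columns and libraries were made with a TruSeq stranded mRNA kit. Wild type gave 1 library per treatment, and each treatment of the mutant cells gave 2 libraries, 1 per clone. Groups, clone numbers and treatments were taken from the labels. Nothing in the labels says that libraries of a line were separate cultures, so p-values measure the spread between these clones and samples.

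The deposited values are FPKM (fragments scaled by transcript length and by the number of mapped fragments), as computed by the authors, 1 value per gene symbol and library. The submitters' processing notes list HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff, with no version for the last. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are given and antisense or overlapping genes may share fragments. Of 41401 symbols, 38797 matched the RefSeq names of assembly UU_Cfam_GSD_1.0, which was used for names only. No transcript of the mitochondrial genome was among the symbols. No pair of libraries held identical values.

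FPKM values hide the number of fragments, so the absolute depth is unknown. Relative depth was read from low values, since in Cufflinks output a gene covered by a few fragments takes values near whole multiples of what 1 fragment is worth. Between 35.0% and 38.2% of the ratios of low genes (below 0.1 FPKM) fell within 0.01 log2 units of ratios of small whole numbers, against 5.4% to 6.2% on a shifted grid. Relative to the wild-type control library, depth was 0.861 in the wild-type knockdown library, 0.853 and 0.768 in the control and knockdown libraries of clone 1, and 0.916 and 0.868 in those of clone 2. The values are not whole multiples for most genes, so no counts were rebuilt and no count model was run.

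All tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, 12125 in all, of which 11873 matched a RefSeq name. A model with 4 groups was fitted to all 6 libraries, with moderated variances and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Contrasts were the knockdown effect in the clones, the difference between clones and wild type under control siRNA, and the difference between the knockdown effects of clones and wild type (the interaction). With 2 residual degrees of freedom and a prior of 1.95, the spread came from the 2 mutant groups, and each lone wild-type library was assumed to vary like them. Knockdown in wild-type cells alone was 1 library against 1 and was given no p-value.

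The design fixed before the data were examined had no clone term, and the fit with the clone as block was listed beside it. The numbers do pair the samples, because libraries with the same number come from the same clone. Their deviations from the group means correlated with r = 0.595 across genes. The paired fit has 1 residual degree of freedom and a prior of 3.23. In the text, "rose" and "fell" refer to the knockdown in clones in this paired fit, and fits without pairing are named as such. The genotype difference lies between lines and has no paired version.

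Gene lists, 26 in number, were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the 23 lists with at least 3 measured genes. In the lone wild-type pair, and likewise in each clone, a list's median was placed among 10000 random lists of the same size matched on mean expression. None of the 21 list calls over the 3 contrasts held with an estimated correlation. That correlation comes from the residuals, with 2 degrees of freedom unpaired and 1 paired, so this form of camera could hardly pass any list. Its smallest unadjusted p in the unpaired fit was 0.0443, and its failures decide little for or against a list. None of the 21 list calls passed by fry either. The smallest fry adjusted p among them was 0.0939 without pairing, for ribosome biogenesis after knockdown in the clones. With pairing it was 0.117, for lysosome genes after knockdown in the clones. Genes to be named were also set by rule beforehand: PRL and CNNM genes, the 10 largest rises and 10 largest falls in the clones with at least 5 FPKM in the higher group, 5 per direction in the other comparisons, and up to 4 members of a list. Genes at unnamed loci were tested but are not named. The named-gene places in the unpaired comparisons were filled, as the rule provides, by genes that did not pass.

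The procedure was tested on simulated data with the gene means of the real libraries and their median spread within and between lines. Genes were drawn independently and without an intensity trend, so the rates found need not hold for the real libraries, where the unpaired fit called 0 genes. For the knockdown in clones over 12125 genes, 0 genes were called without an effect in either fit. With 200 genes shifted by 1 log2 unit and the 27 lysosome genes by 0.5, the unpaired fit recovered 82% of the 200 and 0 of the 27 with 2 false calls, and the paired fit recovered 98% of the 200 and 23 of the 27 with 16 false calls among 235. Alternatives covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), median-of-ratios and quantile scaling, the variance model, the clone block, the mutant libraries alone and each mutant library left out. A further 25 settings, mostly of the paired fit and among them filters at a mean of 0.1 and 0.5 FPKM, were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.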

Results

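The series asks how MDCK cells, a polarised epithelial line from canine kidney, respond to loss of PRL phosphatases in a study of falling cellular magnesium and NF-κB-dependent cell death. PRL1 and PRL2, encoded by PTP4A1 and PTP4A2, are small phosphatases that bind the CNNM family of magnesium transporters. Transcripts were measured as FPKM in 6 libraries: wild-type cells and 2 clones lacking PRL2 and heterozygous for PRL1, each given control or PRL1 siRNA. Between 22961 and 23964 gene symbols were above 0 in a library, and 11908 to 12209 reached 1 FPKM. The absolute depth is unknown, and the shallowest library, the knockdown library of clone 1, had 0.768 of the depth of the wild-type control library. The most abundant gene was LGALS3, which encodes galectin-3, in wild type and SPP1, which encodes osteopontin, in both clones.

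The targeted transcript was lower in all 3 knockdown libraries. PTP4A1 went from 63.5 to 33.1 FPKM in wild type, from 61.7 to 37.8 in clone 1 and from 69.9 to 37.8 in clone 2. In the clones this was a log2 fold change of -0.78 ± 0.05 (SE, n = 2 clones, limma with the clone as block, adjusted p = 0.00638; 0.106 without pairing). PTP4A2 remained at 80.4 FPKM in clone 1 and 56.7 in clone 2 under control siRNA, against 72.7 in wild type, and PTP4A1 was at 61.7 and 69.9 FPKM in the clones against 63.5 in wild type. The labels do not say how the alleles were disrupted, and a transcript level does not report a small change in sequence, so these values do not check the genotype labels. PTP4A2 also fell by 0.22 ± 0.03 after knockdown of PRL1 (paired limma, adjusted p = 0.0156; 0.659 without pairing), a value between 0.03 and -0.47 in unpaired fits without 1 mutant library.

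**Figure D1:**
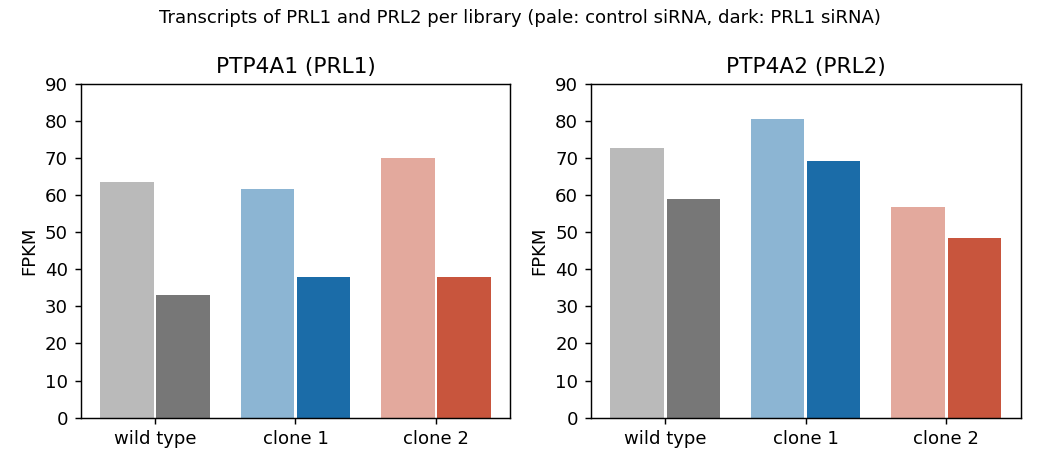
FPKM of PTP4A1 (left) and PTP4A2 (right) in each of the 6 libraries, with pale bars for control siRNA and dark bars for PRL1 siRNA, 1 library per bar. PTP4A1 is between 61.7 and 69.9 FPKM in the control libraries and between 33.1 and 37.8 in the knockdown libraries.

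Among other magnesium-related genes, the CNNM transporters changed little. CNNM3 rose by 0.25 ± 0.05 log2 units in the clones (paired limma, adjusted p = 0.0264; 0.337 without pairing), while CNNM2 (0.19 ± 0.11, adjusted p = 0.247) and CNNM4 (-0.03 ± 0.04, adjusted p = 0.565) did not pass. CNNM4 was at 11.8 and 9.08 FPKM in the control libraries of the clones. PTP4A3, which encodes PRL3, did not exceed 0.49 FPKM and CNNM1 did not exceed 0.00376 FPKM in any library. Of 23 measured genes of PRL phosphatases and magnesium transport, 3 rose and 5 fell in the paired fit, and adjusted over the list alone the counts were also 3 and 5. Over all genes this fit called 4092 of 12125. The list holds PTP4A1, the target of the siRNA, and PTP4A2. Both are among the falls and enter the list tests. SLC41A1, a magnesium exporter, rose by 0.53 ± 0.06 (adjusted p = 0.00912) and NIPA1, a magnesium transporter, fell by 0.44 ± 0.06 (adjusted p = 0.0135). The list did not stand apart from other genes by camera (adjusted p = 0.726), whereas fry, which asks whether members move on balance one way, gave a downward result without pairing (adjusted p = 0.0211) that did not hold with pairing (adjusted p = 0.216).

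Among named genes, the largest rises after PRL1 knockdown in the clones were in MMP13, TXNIP and CCL5. TXNIP, which encodes a thioredoxin-binding regulator of glucose uptake, rose from 8.52 ± 3.57 to 130.5 ± 49.4 FPKM (SD, n = 2), a log2 fold change of 3.79 ± 0.04 (SE, adjusted p = 0.000275). MMP13, a collagenase, rose by 4.17 ± 0.19 (adjusted p = 0.00607), from 1.98 to 68.7 FPKM in clone 1 and from 28.8 to 410 in clone 2. The chemokine CCL5 rose from 0.344 ± 0.423 to 16.6 ± 7.80 FPKM, CCL7 from 2.17 ± 1.17 to 13.4 ± 1.21 and CCL2 from 57.9 ± 6.59 to 216 ± 58.5 (adjusted p = 0.00607, 0.00638 and 0.00909). PLAT, the tissue plasminogen activator, rose by 2.33 ± 0.32, VMO1 by 1.59 ± 0.05, and the MHC class II genes DLA-DQB1 and DLA-DQA1 by 1.53 ± 0.05 and 1.47 ± 0.09. The microRNA locus MIR8856, very short for an mRNA library, was listed at 0 in both clone control libraries and at 3.36 and 13.4 FPKM after knockdown.

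The deepest falls were in genes of endoplasmic reticulum stress. HERPUD1, a component of ER-associated degradation, fell by 2.46 ± 0.08 log2 units, from 119 to 18.6 FPKM in clone 1 and from 73.0 to 13.9 in clone 2 (adjusted p = 0.00607). DDIT3, which encodes the transcription factor CHOP, fell by 2.30 ± 0.16, CHAC1, a glutathione-degrading enzyme, fell by 2.24 ± 0.11 and the secreted hormone FGF21 fell by 1.92 ± 0.10 (adjusted p = 0.00635, 0.00609 and 0.00609). Among known targets of YAP and TAZ, CCN1 fell by 1.98 ± 0.05 and ANKRD1 fell by 2.195 ± 0.22, and WWTR1, which encodes TAZ, fell by 1.30 ± 0.04 (adjusted p = 0.00607, 0.00867 and 0.00607). CAR1 fell by 1.44 ± 0.07 and the tissue factor gene F3 by 1.48 ± 0.10.

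**Figure D2:**
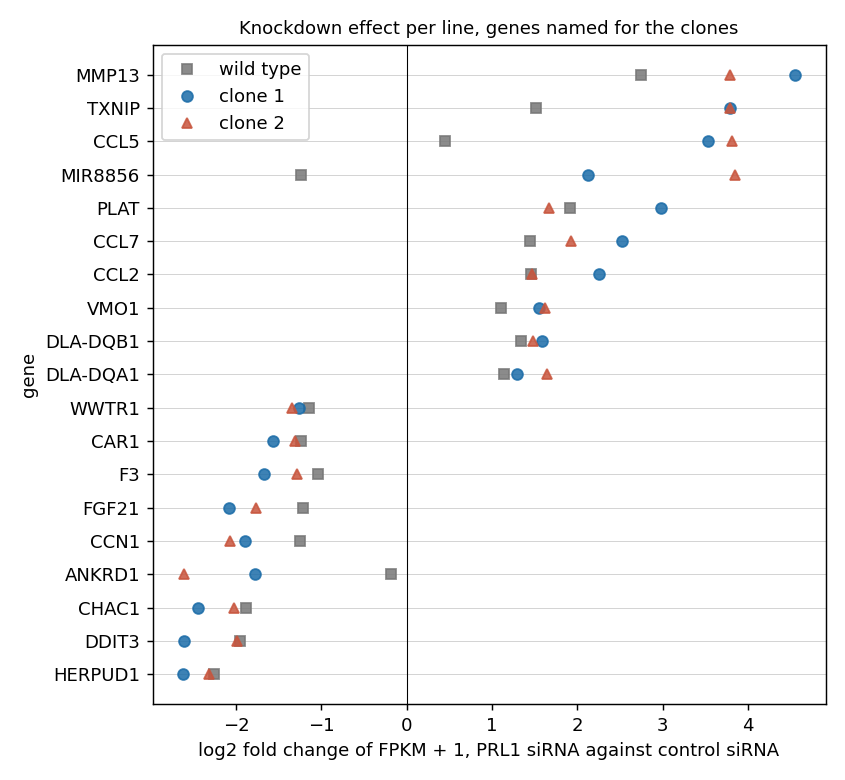
Log2 fold change of FPKM + 1 (x axis) for the genes named with the largest rises and falls in the clones (y axis), with 1 point per line: squares for wild type, circles for clone 1 and triangles for clone 2. TXNIP is at 3.79 in both clones and 1.51 in wild type, and HERPUD1 is between -2.62 and -2.25 in all 3 lines.

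Over all genes, the paired limma fit called 4092 of 12125 genes in the clones, 1762 higher and 2330 lower, with a median absolute log2 fold change of 0.296. Of these, 90 changed at least 2-fold, 53 up and 37 down. Without pairing, limma called 0 genes (smallest adjusted p = 0.106), with 2575 genes at an unadjusted p under 0.05 where 606 are expected by chance. The paired count was 0 when all 27931 genes above 0 were tested (smallest adjusted p = 0.159), and it rests on 1 residual degree of freedom.

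Genes of the integrated stress response and unfolded protein response fell together. Of 34 measured genes, 26 fell, 1 rose and 7 did not pass in the paired fit; adjusted over the list alone, 27 fell and 2 rose, and without pairing 0 passed over all genes and 23 fell over the list alone. The ER chaperone HSPA5 went from 540 to 198 FPKM in clone 1 and from 361 to 150 in clone 2 (-1.35 ± 0.05, adjusted p = 0.00607). ATF4, the central transcription factor of the response, fell by 0.73 ± 0.05 and the amino acid transporter gene SLC7A5 was at -0.95 and -1.05 in the 2 clones (adjusted p = 0.00635 and 0.00607). The member that rose was ATF5 (0.43 and 0.44, adjusted p = 0.0109), also a transcription factor of the stress response. The list's median was -0.48 (camera adjusted p = 3.67e-08, and adjusted p = 0.935 with an estimated correlation). By fry the list did not pass (adjusted p = 0.287 without pairing and 0.216 with pairing).

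NF-κB target genes and cytokine genes were higher. Of 28 measured NF-κB targets, 13 rose and 2 fell in the paired fit, and adjusted over the list alone 16 rose and 3 fell (7 and 2 without pairing). NFKBIA, which encodes the inhibitor IκBα, rose from 20.4 to 59.6 FPKM in clone 1 and from 17.05 to 38.3 in clone 2 (1.31 ± 0.10, adjusted p = 0.00685). MMP9 rose by 1.34 ± 0.15, TNFAIP3, which encodes the feedback inhibitor A20, by 1.07 ± 0.07 and TNFAIP2 by 0.90 ± 0.05 (adjusted p = 0.0101, 0.00635 and 0.00635). The members that fell were GADD45B, a stress-inducible growth regulator, and PLAU, the urokinase gene. The median of the list was 0.28 (camera adjusted p = 0.000136, and adjusted p = 0.935 with an estimated correlation). Of 17 cytokine and chemokine genes, 11 rose, 1 fell and 5 did not pass, with 12 and 1 adjusted over the list alone (9 and 0 without pairing). IL6 went from 0.0939 to 2.55 FPKM in clone 1 and from 0.825 to 5.27 in clone 2 (1.74 ± 0.09, adjusted p = 0.00633). EDN1, which encodes the vasoconstrictor endothelin-1, was the member that fell (-1.30 ± 0.12, adjusted p = 0.00762). The cytokine list had a median of 1.05 (camera adjusted p = 3.62e-05, and adjusted p = 0.935 with an estimated correlation).

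Components of the NF-κB pathway moved both ways, 6 rising and 5 falling of 31 (6 and 5 adjusted over the list alone, camera adjusted p = 0.736). Over all genes the paired fit called 4092 of 12125, so calls of single members do not by themselves set a list apart. The kinase gene IKBKB rose by 0.48 ± 0.04, while RIPK1 fell by 0.52 ± 0.04 and MALT1 by 0.50 ± 0.06 (adjusted p = 0.00735, 0.00735 and 0.0107). Among 8 measured genes of lytic cell death, 2 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.736). NINJ1, which mediates plasma membrane rupture, rose by 0.61 ± 0.04, and the necroptosis kinase gene RIPK3 fell by 0.36 ± 0.05 (adjusted p = 0.00635 and 0.0124). Among 26 apoptosis regulators 5 rose and 4 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.984). The survival gene BCL2 fell by 0.88 ± 0.06 and BCL2L11, which encodes the pro-apoptotic BIM, rose by 0.88 ± 0.06 (adjusted p = 0.00635 for both). Of 21 p53 targets, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.236), and of 25 genes of oxidative stress and ferroptosis 6 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.736). In the latter, ACSL4, a lipid enzyme of ferroptosis, rose by 0.85 ± 0.05 and TXNRD1, thioredoxin reductase, fell by 0.63 ± 0.06 (adjusted p = 0.00635 and 0.00751).

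Proliferation and ribosome genes were lower. Of 32 genes of G2 and mitosis, 23 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 3e-06). ANLN, a cytokinesis scaffold, fell by 0.48 ± 0.03 (adjusted p = 0.00635). Of 30 genes of S phase, 18 fell and 0 rose (22 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.00043), led by the replication licensing gene CDC6 (-0.81 ± 0.04, adjusted p = 0.00607); without the knockdown library of clone 2 the S phase list had an adjusted p of 0.0621. Ribosome biogenesis genes fell in 18 of 26 cases and rose in 0 (20 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 1.58e-06), among them NOP56 (-0.39 ± 0.04, adjusted p = 0.00776). Of 36 cytosolic ribosomal protein genes, 18 fell and 0 rose (26 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 0.000136). Without pairing, 9 ribosome biogenesis genes fell adjusted over the list alone, and 0 genes passed in the lists of G2 and mitosis, S phase and ribosomal proteins. Each of these lists had an adjusted p = 0.935 with an estimated correlation.

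Medians were above 0 by less in the lists of lysosome, cholesterol synthesis and respiratory chain genes. Of 27 lysosome genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.000174), with the protease genes CTSD (0.45 ± 0.03) and CTSB (0.38 ± 0.04) leading (adjusted p = 0.00638 and 0.0081). Of 23 cholesterol synthesis genes, 8 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.0459). MVD rose by 0.48 ± 0.03, and MSMO1 fell by 0.50 ± 0.07. Of 28 respiratory chain genes, 5 rose and 1 fell (0 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.0364). Without pairing, 0 genes of these 3 lists passed adjusted over the list alone. Each had an adjusted p = 0.935 with an estimated correlation. The cholesterol call was lost with no filter (adjusted p = 0.113), without the control library of clone 1 (0.255) and without its knockdown library (0.163), and the respiratory chain call without the control library of clone 2 (0.286) or the knockdown library of clone 1 (0.875); both gave 0.0611 without an intensity trend.

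Other lists did not pass by camera. For interferon response genes 10 rose and 12 fell of 30 (10 and 13 adjusted over the list alone, adjusted p = 0.875), for glycolysis and hypoxia 3 and 4 of 26 (3 and 4, adjusted p = 0.736), for immediate early genes 9 and 7 of 26 (10 and 9, adjusted p = 0.726) and for heat shock 2 and 6 of 18 (4 and 6, adjusted p = 0.984). For epithelial junction and keratin genes 10 rose and 7 fell of 30 (10 and 10, adjusted p = 0.736), with the kidney cadherin gene CDH16 rising by 0.88 ± 0.12 (adjusted p = 0.0134). For mesenchymal genes 5 rose and 3 fell of 14 (7 and 3, adjusted p = 0.736). Markers of other cell types were mostly under 1 FPKM on average: 3 leukocyte, 2 fibroblast and 1 endothelial gene were measured, too few for a test in the last 2 lists. CD74, which epithelial cells with MHC class II also express, was the leukocyte marker that rose (0.44 ± 0.04, adjusted p = 0.00751; camera for the list, adjusted p = 0.726), COL5A1 of the fibroblast list fell by 0.26 ± 0.04 (adjusted p = 0.019), and FLT1, the endothelial gene, did not pass (0.00422 ± 0.04, adjusted p = 0.948). Median, mean and test did not share a sign in the lists of NF-κB pathway components, apoptosis, immediate early, interferon, epithelial, heat shock and leukocyte genes.

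**Figure D3:**
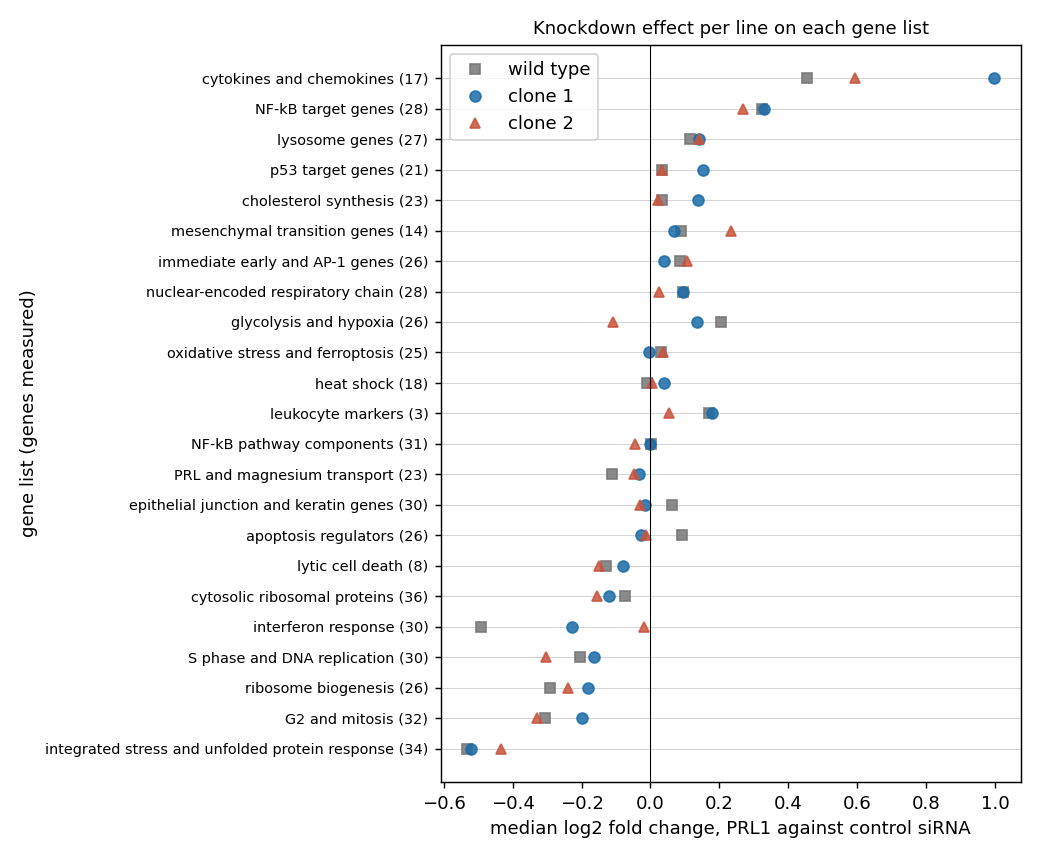
Median log2 fold change after PRL1 siRNA (x axis) of each of the 23 tested gene lists (y axis, genes measured in parentheses), with squares for wild type, circles for clone 1 and triangles for clone 2. The stress response list is lowest in clone 1 (-0.52), clone 2 (-0.43) and wild type (-0.53), and the interferon list is at -0.49 in wild type against -0.23 and -0.02 in the clones.

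In wild-type cells, 1 knockdown library was compared with 1 control library, so the differences have no replicate check. The same stress genes were lower: HERPUD1 was at 148 FPKM under control siRNA and 30.3 after knockdown, DDIT3 at 54.3 and 13.3, CHAC1 at 20.6 and 4.85, HSPA5 at 723 and 222, and CCN1 at 99.8 and 41.4. MMP13 was higher, at 0.492 and 9.05 FPKM. The other genes at the top were very short loci, MIR8800, MIRLET7D, MIR1249 and TRNASTOP-UCA, each listed at 0 in the control library and at 8.38, 5.38, 5.07 and 68.0 FPKM after knockdown; TRNASTOP-UCA was also listed at 0 in 3 of the 4 mutant libraries. In all, 105 genes differed at least 2-fold, 60 up and 45 down, a count that was 176 with a pseudocount of 0.1 and 60 among genes with a mean of at least 5 FPKM.

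The list medians in wild type followed the clones for most lists. The stress response list had a median of -0.53, at percentile 0 of 10000 matched random lists, as did G2 and mitosis (-0.30), ribosome biogenesis (-0.29) and S phase (-0.20). NF-κB targets were at 0.33 and cytokines at 0.45, both at percentile 100; lysosome genes at 0.12 and percentile 99.3; respiratory chain genes at 0.09 and percentile 96.6; ribosomal proteins at -0.07 and percentile 4.4; cholesterol genes at 0.03 and percentile 83.6. Interferon response genes were at -0.49 and percentile 0, with MX1, an antiviral GTPase, at 25.8 FPKM under control siRNA and 12.9 after knockdown. The interferon list was also at percentile 0 in clone 1 (median -0.23), but at 56.5 in clone 2 (-0.02). Glycolysis genes were at 0.21 and percentile 100 in wild type, at percentile 99.9 in clone 1 (0.13) and at 6.1 in clone 2 (-0.11).

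Sizes of effect were compared line by line, each knockdown library against the control library of its own line. At least 2-fold changes numbered 60 up and 45 down in wild type, 92 and 55 in clone 1, and 65 and 50 in clone 2. Both clones shared 31 genes up and 23 down, where independent lists would share 0.49 and 0.23. Clone 1 and wild type shared 35 up (0.46 by independence) and 17 down (0.20), and clone 2 and wild type 18 up (0.32) and 17 down (0.19). Across genes, which are not independent replicates, Pearson's r was 0.55 between the clones, 0.535 between clone 1 and wild type and 0.573 between clone 2 and wild type, with Spearman's rho of 0.79, 0.725 and 0.699. Of the 4092 genes called in the paired fit, 3886 (95%) had the same sign in wild type, against 78% of all genes. The 54 genes shared by both clones became 112 with a pseudocount of 0.1.

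**Figure D4:**
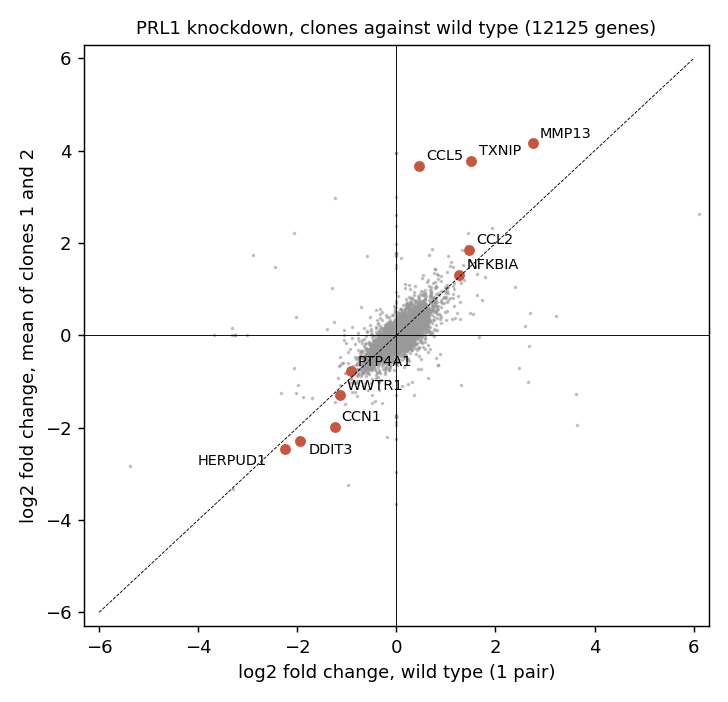
Log2 fold change after PRL1 siRNA for 12125 genes, in the single wild-type pair (x axis) and as the mean of both clones (y axis), with 10 genes marked and the dashed line at equality. HERPUD1 is at -2.25 and -2.46 and NFKBIA at 1.27 and 1.31, near the line, while TXNIP is at 1.51 and 3.79 and CCL5 at 0.45 and 3.68.

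Clones and wild type were next compared under control siRNA. HEPH, which encodes the copper-dependent ferroxidase hephaestin, was at 44.0 FPKM in wild type and at 1.85 and 1.00 in the clones (log2 difference -4.23 ± 0.26, SE). The transcription factor gene IRX2 was at 7.15, 0.0208 and 0.206 FPKM (-2.88 ± 0.17), the tetraspanin gene TSPAN8 at 50.3, 4.01 and 15.1, WDR72 at 15.9, 3.53 and 1.31, and the chemokine receptor gene ACKR3 at 8.40, 1.04 and 0.00999. Higher in the clones were SORBS2, a cytoskeletal adaptor (9.75 FPKM in wild type, 49.6 and 67.8 in the clones), BLNK, an adaptor best known from B cells (2.103, 13.4 and 12.9), PMP22 (1.62, 10.2 and 12.9) and CCL2 (14.8, 53.3 and 62.6), and the microRNA locus MIR8800 was listed at 0 in wild type and at 9.045 and 5.955 in the clones. None of these passed: limma called 0 genes (smallest adjusted p = 0.098), with 1632 at an unadjusted p under 0.05 against 606 by chance, 1138 higher and 494 lower in the clones. With no filter on low values 165 genes were called, 158 of them with a mean under 1 FPKM and BLNK among the rest (adjusted p = 0.0381), and 4 genes without an intensity trend, all at unnamed loci.

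In camera, 6 of 23 lists differed between the genotypes. Both clones were set against the same 1 wild-type control library, so a deviation of that library alone would move both clones one way. Camera ranks a list against other genes and does not measure the spread between wild-type samples. Ribosome biogenesis genes were higher in both clones than in wild type in 26 of 26 cases (median 0.35, adjusted p = 1.06e-12), and 21 passed adjusted over the list alone against 0 over all genes; BOP1 was at 12.4 FPKM in wild type and 19.3 and 20.1 in the clones. Cytosolic ribosomal protein genes were higher in both clones in 35 of 36 cases (median 0.24, adjusted p = 1.53e-09) and heat shock genes in 13 of 18 (median 0.16, adjusted p = 0.00703), with 0 and 1 passing adjusted over the list alone. Stress response genes were lower in both clones in 20 of 34 cases (median -0.20, adjusted p = 8.07e-05) and glycolysis genes in 14 of 26 (median -0.12, adjusted p = 0.000543), with 0 passing adjusted over the list alone in either. The stress response median was -0.08 in clone 1 and -0.31 in clone 2. PFKFB3, an activator of glycolysis, was at 114 FPKM in wild type and 46.0 and 63.5 in the clones. Cytokine genes were higher in 10 of 17 (median 0.42, adjusted p = 0.0308), and 3 passed adjusted over the list alone. The cytokine median was 0.06 in clone 1 and 0.62 in clone 2. With an estimated correlation the cytokine list had an adjusted p = 0.852, and each of the other 5 an adjusted p = 0.815. The glycolysis call was lost with no filter (adjusted p = 0.0594) and the cytokine call without the control library of clone 2 (0.292). The clone control libraries also enter the knockdown effect with opposite sign, so the 2 comparisons share their chance values, and NF-κB targets (median 0.21, adjusted p = 0.071) and lytic cell death genes (median 0.20, adjusted p = 0.0641) did not pass. Among markers of other cell types, FLT1 was at 6.23 FPKM in wild type and 15.5 and 23.8 in the clones, and COL5A1 at 7.565, 16.3 and 23.6. Each passed adjusted over its list alone, of 1 and 2 measured genes, but not over all genes (limma adjusted p = 0.294 and 0.298).

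The last comparison asked whether the knockdown effect differed between clones and wild type. TXNIP went from 8.43 to 25.9 FPKM in wild type, from 5.99 to 95.6 in clone 1 and from 11.05 to 165 in clone 2, a difference of 2.27 ± 0.06 log2 units in the paired limma fit (adjusted p = 0.0242), the only gene called there, with 1228 at an unadjusted p under 0.05. The SE of the paired fit rests on the 2 clone effects, 3.787 and 3.788 for TXNIP, and on the prior. It holds no spread between wild-type pairs. The unpaired fit called 0 genes (smallest adjusted p = 0.474, with 136 at an unadjusted p under 0.05 where chance gives 606). The TXNIP call was lost with quantile scaling (adjusted p = 0.0506), with no filter (0.189) and with filters at a mean of 0.1 or 0.5 FPKM (0.0542 and 0.0518), and over the other settings of the paired fit its adjusted p was 0.00283 to 0.042; these settings were chosen after seeing the data. CCL5 was at 0.0713 and 0.467 FPKM in wild type, against 0.0445 and 11.1 in clone 1 and 0.643 and 22.1 in clone 2 (difference 3.22 ± 0.18, paired adjusted p = 0.0601). MMP13 differed by 1.42 ± 0.33 (paired adjusted p = 0.468), a difference that was -0.24 without the control library of clone 1. NDUFS4, a subunit of respiratory complex I, was at 23.5 and 12.3 FPKM in wild type, 13.3 and 14.8 in clone 1 and 10.4 and 12.4 in clone 2 (difference 1.07 ± 0.08, paired adjusted p = 0.102). ANKRD1 (-2.01 ± 0.38, paired adjusted p = 0.454) did not pass and started at 0.199 FPKM in wild type, where the log2 scale left no room for a similar fall, and MIR8856, MIR8800, MIRLET7D and MIR1249 had differences of 4.22, -2.80, -2.90 and -2.39 with libraries listed at 0. With no filter the unpaired fit called 157 genes, 153 of them with a mean under 1 FPKM, and without an intensity trend 4 genes at unnamed loci.

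By list, interferon response genes differed most. The clone effect lay above the wild-type effect in both clones for 28 of 30 genes (median difference 0.37, camera adjusted p = 1.7e-09), although 0 genes passed over all genes and 13 passed adjusted over the list alone in the paired fit only. IFI44L, an interferon-induced gene, went from 19.3 to 8.28 FPKM in wild type, from 12.9 to 8.43 in clone 1 and from 18.1 to 13.8 in clone 2, and DDX58, which encodes the RNA sensor RIG-I, from 9.08 to 8.89, 8.15 to 12.6 and 10.1 to 15.9. Ribosome biogenesis genes (median 0.09, adjusted p = 0.00141), cytokines (0.16, adjusted p = 0.0353) and cholesterol genes (0.06, adjusted p = 0.0438) also had differences above 0, and glycolysis genes below 0 (-0.13, adjusted p = 0.00138), led by the glucose transporter gene SLC2A1 at 598 and 582 FPKM in wild type, 542 and 363 in clone 1 and 598 and 409 in clone 2. Adjusted over the list alone, 4 cytokine genes and 1 glycolysis gene passed in the paired fit. All 5 lists had an adjusted p = 0.894 with an estimated correlation. The paired fit added ribosomal proteins (median -0.04, adjusted p = 0.0179; 0.0623 without pairing) and G2 and mitosis (median 0.07, adjusted p = 0.036; 0.117 without pairing), whose adjusted p = 0.954 with an estimated correlation. The cytokine and cholesterol calls were lost in at least 1 of the scaling, filter and left-out library settings, and the glycolysis call with no filter (adjusted p = 0.0972) and without the control library of clone 2 (0.249). NF-κB targets did not pass this test (median difference 0.06, adjusted p = 0.67). Both clones were set against the same wild-type libraries here.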

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

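The tests of a weaker knockdown, of library scaling, of low values, of siRNA effects that do not need PRL1, of a deviating wild-type pair, of the wild-type control library and of shared list members were chosen after the results were seen, as were the further settings for TXNIP, while the comparison of the knockdown effects between clones and wild type was set beforehand.

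TXNIP stood out because its knockdown effect differed between clones and wild type in a test of the difference itself, by 2.27 log2 units (paired limma, adjusted p = 0.0242, but 0.0506 to 0.189 with quantile scaling or a lower filter). The spread behind these values comes from the clones and the prior, with none between wild-type pairs. In the fit without pairing, which was the design set beforehand, the difference did not pass (2.27 ± 0.69, limma adjusted p = 1), and CCL5 did not pass in either fit (paired adjusted p = 0.0601). No weaker knockdown was seen in wild-type cells at the transcript level. The PTP4A1 log2 fold change there was -0.92, against -0.69 and -0.87 in the clones. The clone effect minus the wild-type effect was 0.14 ± 0.09 (SE, paired limma), with 1 wild-type pair. Transcript levels do not report functional PRL1, so a weaker loss of it in wild type stays open. Chance deviation of the single wild-type pair stays open: over all genes its Pearson r with the clones was 0.535 and 0.573 against 0.55 between the clones, but its Spearman rho was lower (0.725 and 0.699 against 0.79), and 1 pair cannot settle a single gene. A response that grows as PRL dosage falls, which the genotype groups name, also stays open and was not tested.

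Interferon response genes were set apart by the same test (camera adjusted p = 1.7e-09, and adjusted p = 0.894 with an estimated correlation). Fry did not set them apart (adjusted p = 0.968 without pairing and 0.381 with pairing). The members shared with the NF-κB and cytokine lists, CXCL10 and CCL5, do not account for the camera result, since limma's camera without them gave 1.49e-09 as the unadjusted value. A raised interferon state of the wild-type control library cannot be told apart from a lower state of its knockdown library: the control library was above the clone controls by a median of 0.077 and the knockdown library was at -0.24 against the clone knockdown libraries, with 1 library each.

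Other lists with a tested difference between the knockdown effects were ribosome biogenesis (adjusted p = 0.00141), glycolysis and hypoxia (0.00138), cytokines and chemokines (0.0353) and cholesterol synthesis (0.0438), all by camera without pairing and none with an estimated correlation (adjusted p = 0.894).

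A constant shift of whole libraries does not account for the resemblance of the wild-type response to that of the clones. Such a shift moves genes one way. In all 3 lines, 13 genes were at least 2-fold up and 12 at least 2-fold down. Median log2 fold changes over all genes were -0.00385 in wild type, -0.0121 in clone 1 and -0.0184 in clone 2. A bias that varies with expression level was not tested separately. The smaller correlation across genes after quantile normalization (0.53) decides nothing here, because a correlation ignores a constant shift. Low values do not account for the resemblance either, since the smaller correlation without that normalization was 0.68 among the 4265 genes with a mean of at least 20 FPKM. An effect of the PRL1 siRNA that does not need PRL1 could give the same picture, and the clone effect relative to wild type, 1.11 over all genes, is too near the equal size it predicts to decide. A response to lower PRL1 in every genotype stays open as well and was not tested.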

How the results depend on the processing

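The settings of the paired fit and the filters at 0.1 and 0.5 FPKM, 25 in all, were chosen after seeing the data, and the other alternatives before. Pairing moved the knockdown count in clones from 0 to 4092 and the interaction count from 0 to 1, and apart from the 2 added interaction lists it changed no other list call by camera. With the siRNA labels of clone 2 exchanged, the paired fit called 0 genes; 2 assignments are too few for a share under 0.05. Without a filter the paired count was 0, with 27931 genes tested in place of 12125 and prior degrees of freedom of 0.831 in place of 3.23. The larger number of tests alone does not account for this. More tests raise an adjusted p at most in proportion, and the smallest paired limma adjusted p went from 0.000275 to 0.159. The part of the lower prior was not tested separately. The counts were 2701 and 3760 at minimum means of 0.1 and 0.5 FPKM. With the remaining settings the paired count was 3035 to 4762, and 3579 of the 3826 genes called after quantile scaling were shared with the main paired list. The paired interaction count was 2 with a pseudocount of 0.1, 3 at a mean of at least 5 FPKM, 7 without an intensity trend, 18 with robust variances, and 0 with quantile scaling and with no filter or filters at 0.1 and 0.5 FPKM, so the TXNIP call depended on the setting. The share of higher calls went from 43.1% to 49.9% with median-of-ratios scaling.

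With no filter the genotype and interaction counts were 165 and 157, mostly genes under 1 FPKM, with filters at 0.1 and 0.5 FPKM 5 and 4 (genotype) and 5 and 0 (interaction), and without an intensity trend 4 and 4; the cause was not tested for the latter. With a pseudocount of 0.1 the wild-type count of 2-fold genes was 176 and that shared by both clones 112, and the wild-type count was 60 at a mean of at least 5 FPKM, where fewer genes were counted. Leaving out any 1 mutant library left 0 calls in each unpaired comparison.

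The values that reversed were near 0 or not called, and the cause was not tested. For knockdown in clones without 1 mutant library, PTP4A2 ranged from -0.47 to 0.03 (0.026 without the control library of clone 1 and 0.032 without the knockdown library of clone 2) and CNNM4 from -0.21 to 0.14 (0.13 without the latter). The genotype differences of PTP4A1, PTP4A2 and CNNM3 ranged from -0.041 to 0.14, -0.35 to 0.14 and -0.20 to 0.037, with PTP4A1 at -0.034 after quantile scaling. The MMP13 interaction ranged from -0.24 to 3.08. In other settings 576 gene values kept direction and side of the threshold and 25 passed newly, 24 of them with pairing. Of the list values, 230 kept both and 47 no longer passed, 21 with an estimated correlation, which rests on 2 residual degrees of freedom. Depth is unknown in absolute terms and was lowest in the knockdown library of clone 1, so genes near 1 FPKM carry the least certain folds.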

Other observations

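All genes named here were singled out after their values were seen, and the test of YAP and TAZ targets was chosen after the fall of WWTR1 was seen, with its gene list changed after a first run.

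Some genes of MHC class II, picked after their rises were seen, were read beside DLA-DQA1 and DLA-DQB1; no list of class II genes was fixed or tested. CIITA, the master regulator of class II transcription, went from 2.90 to 7.50 FPKM in clone 1 and from 2.14 to 4.35 in clone 2 (paired limma, log2 fold change 0.94 ± 0.11, adjusted p = 0.0104), and from 1.56 to 2.73 in wild type. DLA-DRA rose by 0.92 ± 0.05 (adjusted p = 0.00635), DLA-DMA by 1.13 ± 0.05 (adjusted p = 0.00607) and DLA-DMB by 1.07 ± 0.10 (adjusted p = 0.00795). In wild type these were higher by 0.70, 0.75 and 0.80 with no replicate check. B2M, the light chain of MHC class I, rose by 0.49 ± 0.03 in the clones (adjusted p = 0.00635), and its wild-type value was 0.13. None passed in the unpaired fit, where the adjusted p was 0.106 to 0.399.

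ARRDC4, the paralog of TXNIP and like it a target of the glucose-sensing factor MondoA, lay under the filter and was not tested. It was at 0.279 and 1.38 FPKM in clone 1, at 0.459 and 2.14 in clone 2 and at 0.240 and 0.250 in wild type, for control and PRL1 siRNA. SPP1 was at 5001 and 6263 FPKM in clone 1 and at 10361 and 10069 in clone 2, against 2150 and 2680 in wild type. Its knockdown effect did not pass (adjusted p = 0.311).

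The fall of WWTR1 with CCN1 and ANKRD1 led to the hypothesis that targets of YAP and TAZ fell in general. A list of 17 further targets was written first, of which 12 were measured, 8 fell in the paired fit, and camera gave an unadjusted limma p of 0.0138 for the clones (0.122 with an estimated correlation). TGFB2 was then taken out, because its value had already been seen in the mesenchymal list. Of the remaining 16 targets, 11 were measured, and 7 fell and 0 rose in the paired fit. Their median log2 fold change was -0.24 in clone 1, -0.37 in clone 2 and -0.15 in wild type, and camera gave an unadjusted limma p of 0.0212 for the clones (0.137 with an estimated correlation). Lower TAZ activity could give this, as could a response to the siRNA, and neither was tested. The wild-type median of the targets comes from 1 pair and was not tested. WWTR1 was lower in wild type as well, at 193 FPKM under control siRNA and 86.4 after knockdown. Its log2 fold change there was -1.15, against -1.30 in the clones (interaction, paired limma, adjusted p = 0.502). YAP1 itself fell by 0.17 ± 0.04 in the clones (adjusted p = 0.0334) and was at 43.2 and 44.3 FPKM in wild type.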
